A study of Mus musculus with 9 samples.

How the data were processed

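Poly-A RNA sequencing was analysed for 9 libraries from mouse acute myeloid leukaemia in which Tet2 and Tet3 had been targeted, 5 with intact Pbrm1 (Pbrm1_WT) and 4 with Pbrm1 knocked out (Pbrm1_KO). Per the labels' protocols, blasts were taken from the bone marrow of leukaemic mice and lysed, and 200 ng of RNA entered a KAPA mRNA library kit before sequencing on a NovaSeq instrument. Groups and replicate numbers were taken from the sample labels. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, part of which may be technical.

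The deposited files hold raw counts, which per the submitters' processing notes came from reads checked with FastQC 0.11.3, aligned with STAR 2.5.2b to the mm9 build and counted per gene with featureCounts 2.0.1. The notes also name DESeq2 1.34.0 and R 4.1.2. The gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads from overlapping, antisense or near-identical genes, such as the major histocompatibility genes and ribosomal protein genes with processed copies, therefore cannot be assigned with certainty. Each file lists 22609 genes by symbol, many of them older symbols. No coordinates are given, because the reference at hand (GRCm38) is not the authors' build; it was used for gene names and transcript properties.

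The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with edgeR's filterByExpr, which left 12055, and libraries were scaled with TMM. Pbrm1_KO was compared with Pbrm1_WT by the quasi-likelihood F test (robust fit, genotype as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. Levels are CPM, counts scaled to library size with the TMM factors, given as mean ± SD, and library totals lay between 29364895 and 47841660 counts. A count of 0 would have allowed a level of up to 0.0627 to 0.102 CPM per library (3 counts of the total), which covers counting error only.

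Before the data were examined, 35 gene lists were fixed, covering interferon responses, antigen presentation, chromatin regulators, blood and stromal cell types, the cell cycle, metabolism, stress and adhesion. Of these, 33 were tested, leaving out the sex-linked list and lists with fewer than 5 tested genes. They were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists, and also with an estimated correlation and with fry. A score per library, the mean log2 CPM (prior count 2) of a list's members, was compared by a two-sided exact permutation test over all 126 splits of the libraries, for which the smallest possible p is 0.0159. List members were matched by symbol, by an alias fixed beforehand or by an unambiguous older symbol.

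The genes named were chosen by a rule fixed beforehand. It takes Pbrm1, Tet2 and Tet3. It then takes the 10 largest increases and the 10 largest decreases among genes past the threshold, with mean log2 CPM above 1 and no overlap between the groups, leaving out predicted models and receptor segments. For each list it takes up to 4 members past the threshold, or, where there were none, up to 2 with the smallest unadjusted p, which are given as values. Not every gene that the rule takes is reported here. Genes named outside the rule are marked as chosen after their values were seen.

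Alternatives fixed beforehand were DESeq2 size factors, library totals, no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, stricter thresholds, 1 surrogate variable (sva 3.50.0), the replicate number as a block, removal of marker genes of other cell types, and leaving out each library. Added after seeing the data were the removal of a smooth trend in GC content and transcript length per library (mgcv 1.9.3, transcript values known for 98.9% of tested genes), the summing of libraries that resembled each other, and the joint removal of Pbrm1_WT replicates 3 and 4. The procedure was tested on simulated counts for the Pbrm1_KO against Pbrm1_WT design over 11950 genes. It recovered 43.4% of 99 genes changed by 1 on the log2 scale and 80.6% of 98 genes changed by 2, with 11 false calls among 133. The simulated libraries and genes were independent of each other. These rates therefore do not cover libraries of shared origin or correlated genes.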

Results

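The series measured gene expression in mouse acute myeloid leukaemia carrying targeted Tet2 and Tet3, with and without knockout of Pbrm1, and its title names interferon signalling. Pbrm1 encodes a bromodomain subunit of the PBAF chromatin-remodelling complex, and Tet2 and Tet3 encode enzymes that oxidise methylated cytosine. Blasts from the bone marrow of leukaemic mice gave 5 Pbrm1_WT and 4 Pbrm1_KO libraries. Totals were 38432100 ± 5543460 counts in Pbrm1_WT (SD, n = 5) and 41901900 ± 4274860 counts in Pbrm1_KO (SD, n = 4), with no difference in an exact permutation test (two-sided p = 0.381). Pbrm1_WT replicate 5 was the shallowest library, with 29364895 counts, and Pbrm1_KO replicate 4 the deepest, with 47841660. Mpo, which encodes the granule enzyme myeloperoxidase, took the largest share of counts in 7 of the 9 libraries. The first principal component, with 31.1% of the variance, placed all 5 Pbrm1_WT libraries on one side of 0 and all 4 Pbrm1_KO libraries on the other. Pbrm1_WT replicate 5 lay near 0, at -4.75 (other Pbrm1_WT libraries -41.4 to -30.5). Pbrm1_KO replicate 2 lay farthest out, at 66.4 (other Pbrm1_KO libraries 22.3 to 34.8). The second component, with 20.9%, set Pbrm1_WT replicate 5 apart, at -73.9, with all other libraries between -13.6 and 30.1. Some libraries of a group resembled each other closely, with r = 0.986 across genes for Pbrm1_KO replicates 3 and 4 and r = 0.984 for Pbrm1_WT replicates 3 and 4. No pair agreed within sampling noise, the smallest chi-square per degree of freedom being 54.8.

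The targeted genes were examined first, as a check of the labels. Pbrm1 averaged 136 ± 41.5 CPM in Pbrm1_WT (SD, n = 5) and 48.8 ± 21.1 CPM in Pbrm1_KO (SD, n = 4). Its levels were 104, 139, 118, 114 and 207 CPM in Pbrm1_WT replicates 1 to 5 and 70.8, 44.0, 58.7 and 21.7 CPM in Pbrm1_KO replicates 1 to 4, so that every knockout library lay below every Pbrm1_WT library. The log2 fold change was -1.48 (SE 0.33), and edgeR's adjusted p of 0.0543 narrowly missed the threshold. DESeq2 (adjusted p = 0.000775) and limma-voom (adjusted p = 0.010) called it lower. Tet2 stood at 71.3 ± 10.1 CPM in Pbrm1_WT and 78.6 ± 25.5 CPM in Pbrm1_KO, a log2 fold change of 0.14 (SE 0.20, edgeR adjusted p = 0.740). Tet3 stood at 133 ± 24.9 and 162 ± 36.2 CPM, a log2 fold change of 0.29 (SE 0.19, edgeR adjusted p = 0.442). Neither difference exceeded the spread between libraries.

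**Figure D1:**
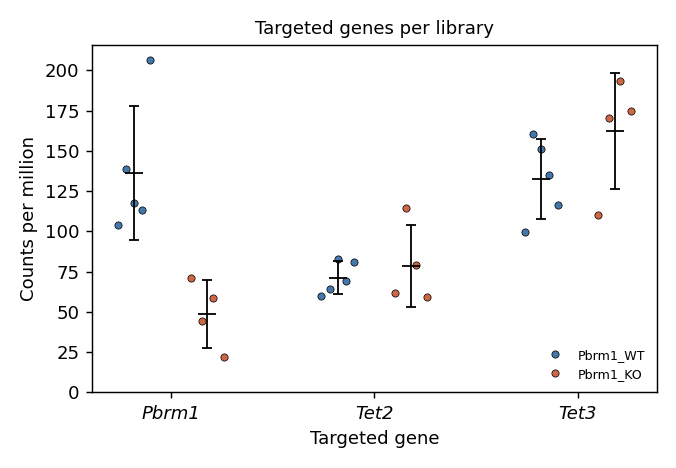
Levels in CPM of the 3 targeted genes, with one point per library, blue for Pbrm1_WT (n = 5) and orange for Pbrm1_KO (n = 4), and bars giving the mean ± SD. Pbrm1 lies between 21.7 and 70.8 CPM in the knockout libraries and between 104 and 207 CPM in the others, while Tet2 and Tet3 overlap.

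Across the transcriptome, 205 of 12055 tested genes differed between the groups, 98 higher and 107 lower in Pbrm1_KO. The largest increases included Prss34, a serine protease of basophils and mast cells, at 1.06 ± 0.71 CPM in Pbrm1_WT and 29.7 ± 23.5 CPM in Pbrm1_KO (log2 fold change 4.81, SE 0.71, edgeR adjusted p = 0.0175). Jag1, a ligand of Notch receptors, rose from 0.435 ± 0.255 to 7.45 ± 2.69 CPM (log2 fold change 4.105, SE 0.50, adjusted p = 0.0111). Sox12, a transcription factor of the SoxC group, rose from 1.05 ± 1.03 to 16.0 ± 2.44 CPM. The sorting nexin gene Snx7 had the largest fitted log2 fold change, 5.06 (SE 0.82), from a Pbrm1_WT level of only 0.212 CPM. Tchh, Ptpdc1, Rnf128, Fert2, Zfyve28 and Aldh5a1, in order of size, completed the 10 largest increases, with log2 fold changes from 3.79 down to 2.45. Without Pbrm1_KO replicate 2 the log2 fold change of Ptpdc1 went from 3.73 to 2.51 and that of Rnf128 from 3.72 to 2.67. Of the 9 fits that each left out 1 library, Ptpdc1 missed the threshold in 8 and Rnf128 in 7.

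Among the decreases, Spint2, which encodes an inhibitor of serine proteases, fell from 42.2 ± 21.0 to 3.42 ± 0.664 CPM (log2 fold change -3.62, SE 0.42, edgeR adjusted p = 0.00969). As3mt, an arsenite methyltransferase, fell from 22.7 ± 8.51 to 0.750 ± 0.639 CPM (log2 fold change -4.91, SE 0.67, adjusted p = 0.0124). Cd79b, which encodes a signalling chain of the B-cell receptor, fell from 27.6 ± 21.3 to 1.41 ± 0.536 CPM (log2 fold change -4.29, SE 0.61, adjusted p = 0.0141). Perp, a p53-responsive membrane protein gene, was the most abundant of the group and fell from 176 ± 64.8 to 18.6 ± 9.91 CPM (log2 fold change -3.24, SE 0.44, adjusted p = 0.0124). Aff3 fell from 22.2 ± 16.3 to 1.92 ± 1.19 CPM. Serpini1, Nynrin, Gpr171, Sdr39u1 and F2rl3, the last encoding a thrombin-activated receptor, completed the 10 largest decreases.

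**Figure D2:**
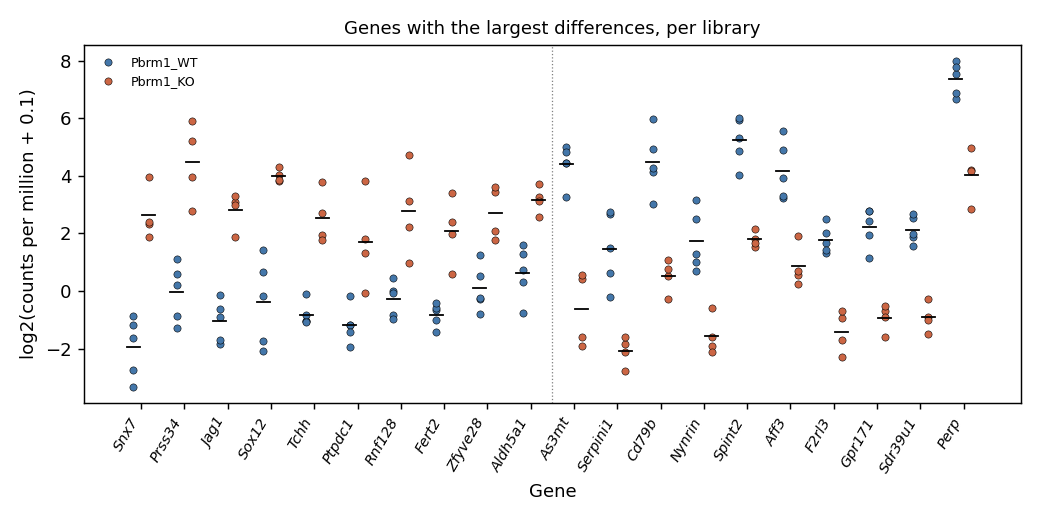
Level of the 10 genes with the largest increases (left of the dotted line) and the 10 with the largest decreases (right) on a log2 axis of CPM plus 0.1, with one point per library and black lines at group means. For each of these genes the 4 Pbrm1_KO libraries (orange) lie on one side of the 5 Pbrm1_WT libraries (blue), as the rule for naming them required.

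Of the 205 genes, 203 showed no overlap between the groups. Over all tested genes 1342, or 11.1%, did not overlap. For random splits of independent libraries the calculated share is 1.59%. The libraries are not shown to be independent, and a shared origin of similar libraries would raise that share. Fold changes of at least 2 were found for 56 of the higher and 83 of the lower genes. The number of genes past the threshold depended strongly on the tool and on single libraries. DESeq2 gave 1093 and limma-voom 2649, while leaving out 1 library gave between 9 (without Pbrm1_KO replicate 4) and 473 (without Pbrm1_WT replicate 5), and leaving out both Pbrm1_WT replicates 3 and 4, a choice made after seeing the data, gave 16. The replicate number as a block gave 6. Summing similar libraries into 3 samples against 2, also chosen after seeing the data, gave 0, with none of the 20 genes named above past the threshold. At an unadjusted p below 0.05 the summed samples gave 1030 genes, against 2389 of 12055 in the main fit. All 205 kept their direction under DESeq2 and limma-voom, which is largely built in, since 203 of them did not overlap. Jag1, Prss34, Spint2 and Perp stayed past the threshold without any 1 library. With Pbrm1_WT replicates 3 and 4 both left out, Spint2, As3mt and Cd79b were the 3 of the 20 genes that stayed past it, and Jag1, Prss34 and Perp missed it (adjusted p = 0.0541, 0.0547 and 0.0547); with the replicate number as a block Spint2 alone stayed.

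Interferon-responsive genes were fitted lower in Pbrm1_KO as a group, but the difference did not exceed the spread between libraries. Of 70 tested interferon-stimulated antiviral genes, none passed edgeR's threshold over all genes or adjusted over the list alone, although 21 were lower and 0 higher at an unadjusted p below 0.05. DESeq2 called 12 of them lower and limma-voom 28. Oas3, which encodes a sensor of double-stranded RNA, stood at 15.4 ± 6.63 CPM in Pbrm1_WT and 4.64 ± 2.44 CPM in Pbrm1_KO (edgeR adjusted p = 0.0690). Cmpk2, a mitochondrial nucleotide kinase gene, stood at 45.1 ± 9.43 and 25.3 ± 6.96 CPM (edgeR adjusted p = 0.0858). The mean log2 fold change of the list was -0.69 (camera adjusted p = 1.54e-05 at the preset correlation), and the adjusted p was 0.629 with an estimated correlation.

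Scored per library, the interferon-stimulated list differed by -0.60 log2 units, Pbrm1_KO minus Pbrm1_WT (exact permutation p = 0.143, two-sided; 0.277 adjusted over 33 lists). The highest scores were 4.92 and 4.83 in Pbrm1_WT replicates 3 and 4, while the other Pbrm1_WT libraries lay between 3.68 and 4.1001 and the Pbrm1_KO libraries between 3.25 and 3.89. Only 1 Pbrm1_KO library lay below every Pbrm1_WT library. Without Pbrm1_WT replicates 3 and 4, which were picked for their scores, so that a smaller difference is built in, the mean log2 fold change was -0.15 and the list was not called (camera adjusted p = 0.288). In Pbrm1_WT replicates 3 and 4 the mean of the B, T and NK cell marker scores was also the highest of all libraries, at 1.19 and 1.04. Pbrm1_WT replicate 1, with the next interferon score, had the lowest mean marker score of its group, -0.079. The interferon-gamma-inducible GTPase list behaved alike, with a mean log2 fold change of -0.65 over 20 genes, 0 members past edgeR's threshold and 7 lower at an unadjusted p below 0.05 (3 by DESeq2, 6 by limma-voom). Its camera adjusted p was 0.00551 at the preset correlation, 0.629 with an estimated correlation and 0.0723 without Pbrm1_WT replicate 3, where the mean was -0.43. In that list Gbp4 stood at 1.28 and 0.350 CPM and Ifi47 at 37.9 and 24.1 CPM in Pbrm1_WT and Pbrm1_KO.

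The list of interferon signalling components was not called (camera adjusted p = 0.282). It was called in 1 of 20 alternative settings (camera adjusted p = 0.0107). In this list the receptor gene Ifngr1 stood at 371 ± 78.5 CPM in Pbrm1_WT and 598 ± 230 CPM in Pbrm1_KO (edgeR adjusted p = 0.178). In the nucleic acid sensing list, which was not called (camera adjusted p = 0.921), Ikbke, a kinase upstream of interferon induction, was the 1 of 29 members past the threshold and rose from 62.5 ± 9.40 to 101 ± 7.82 CPM (log2 fold change 0.69, SE 0.14, edgeR adjusted p = 0.0397).

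**Figure D3:**
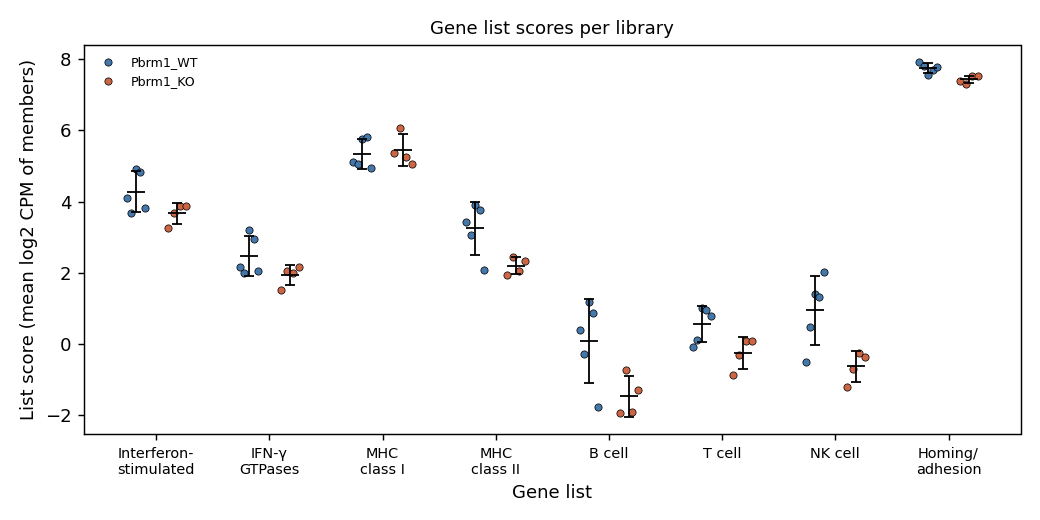
Score of 8 gene lists, the mean log2 CPM of their members, with one point per library, blue for Pbrm1_WT (n = 5) and orange for Pbrm1_KO (n = 4), and bars giving the mean ± SD. The interferon-stimulated score reaches 4.92 and 4.83 in 2 Pbrm1_WT libraries, and the remaining libraries of both groups overlap; homing and adhesion scores, alone among the 8 lists shown, do not overlap.

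Among antigen presentation genes, the class II list was called lower by camera and the class I list was not; the difference between the lists was not tested. The class II list had a mean log2 fold change of -1.21 over 10 genes (camera adjusted p = 0.00168; adjusted p = 0.503 with an estimated correlation). Its highest scores were again in Pbrm1_WT replicates 3 and 4, without which the mean was -0.67 and the call was lost (camera adjusted p = 0.105), and Pbrm1_WT replicate 5, at 2.07, scored below Pbrm1_KO replicates 2 and 4, at 2.45 and 2.33. H2-Oa, a subunit of a peptide-loading regulator, fell from 24.5 ± 15.3 to 5.64 ± 0.452 CPM (edgeR adjusted p = 0.0412) as the 1 member past the threshold, against 7 adjusted over the list alone. The class I list was not called (camera adjusted p = 0.908), its mean of 0.18 and median of 0.04 being positive while camera's direction was down. Without Pbrm1_KO replicate 2 its mean was -0.19, and with limma-voom the list was called lower (mean -0.42, camera adjusted p = 0.000758). None of its 22 members passed edgeR's threshold (2 higher and 4 lower at an unadjusted p below 0.05), against 2 lower and 1 higher by DESeq2 and 7 lower and 1 higher by limma-voom. H2-T24 stood at 21.6 and 11.9 CPM and Psme2 at 39.1 and 27.95 CPM in Pbrm1_WT and Pbrm1_KO, neither past edgeR's threshold.

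Lists of lymphoid markers were among the lowest. The B-cell list had a mean log2 fold change of -1.89 (camera adjusted p = 5.07e-07; adjusted p = 0.458 with an estimated correlation), with Cd79b past the threshold and 6 of 20 members adjusted over the list alone. The NK and cytotoxic list had a mean of -2.13 (camera adjusted p = 1.43e-05; adjusted p = 0.458 with an estimated correlation), with 8 of 14 lower adjusted over the list alone. Its 1 member past the threshold over all genes, the chemokine gene Xcl1, fell from 1.25 ± 0.904 to 0.0791 ± 0.0559 CPM (edgeR adjusted p = 0.0487). The T-cell list had a mean of -0.90 (camera adjusted p = 0.000216; adjusted p = 0.531 with an estimated correlation), with 0 members past edgeR's threshold, 9 lower at an unadjusted p below 0.05, 6 lower by DESeq2, and 7 lower and 1 higher by limma-voom. In it Cd247 stood at 1.16 and 0.346 CPM in Pbrm1_WT and Pbrm1_KO. Without Pbrm1_WT replicates 3 and 4 the B-cell mean was -1.08, the NK mean -1.53 and the T-cell mean -0.60, each still called (camera adjusted p = 0.00220, 0.00974 and 0.0381). Scores of the groups overlapped in all 3 lists: Pbrm1_WT replicate 5, at -1.77 for B cells, lay below Pbrm1_KO replicates 2 and 4, at -0.74 and -1.29, and Pbrm1_WT replicate 1 lay below Pbrm1_KO replicates 3 and 4 for T cells (-0.10 against 0.084 and 0.092) and NK cells (-0.51 against -0.25 and -0.37). The plasma-cell list was not called (camera adjusted p = 0.982).

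Myeloid and other blood lineage lists followed. The mast, basophil and eosinophil list had a mean log2 fold change of -1.08 (camera adjusted p = 0.00217; adjusted p = 0.458 with an estimated correlation), with Prss34 raised as above and Siglec5, listed under its older symbol, reduced from 232 ± 36.4 to 79.3 ± 36.2 CPM (edgeR adjusted p = 0.0280). With the trend in GC content and transcript length removed the mean was -0.80 and the call was lost (camera adjusted p = 0.0692). The erythroid, dendritic-cell, tissue-macrophage, neutrophil-maturation and stromal lists were also called lower by camera, with adjusted p values of 0.00907, 0.0317, 0.0129, 0.0129 and 0.0317. With an estimated correlation these became adjusted p = 0.458, 0.458, 0.660, 0.683 and 0.458, and none of their members passed edgeR's threshold, with 6, 3, 4, 9 and 4 lower at an unadjusted p below 0.05, 3, 2, 2, 3 and 2 by DESeq2 and 2, 4, 2, 1 and 5 by limma-voom. These lists hold 16, 8, 19, 25 and 18 tested genes. Over all genes, 2389 of 12055 had an unadjusted p below 0.05 in either direction. At an unadjusted p below 0.05, 1 erythroid gene was higher, and limma-voom called 1 erythroid, 2 neutrophil-maturation and 1 stromal gene higher, more than it called lower in the neutrophil list. The erythroid call was lost with limma-voom (mean -0.73, camera adjusted p = 0.0890), and leaving out 1 library ended several of the others. The neutrophil list, with a mean of -0.87, was at -0.46 without Pbrm1_WT replicate 1 (camera adjusted p = 0.236) and -0.62 without Pbrm1_KO replicate 1 (0.137). The macrophage list, at -0.59, was at -0.41 without Pbrm1_WT replicate 1 (0.118) and -0.35 without Pbrm1_KO replicate 2 (0.397), and at -0.25 with limma-voom (0.377), which put the neutrophil list at -0.44 (0.249). The dendritic-cell call was lost without Pbrm1_WT replicate 3 (0.0723), Pbrm1_KO replicate 2 (0.0581) or Pbrm1_KO replicate 3 (0.0585), and the stromal call without Pbrm1_WT replicate 3 (0.0723), Pbrm1_WT replicate 5 (0.0507) or Pbrm1_KO replicate 1 (0.0690). With Pbrm1_WT replicates 3 and 4 both left out, the dendritic-cell mean went from -0.85 to -0.41 (0.234) and the stromal mean from -0.72 to -0.35 (0.264). Among them Itgax stood at 26.4 ± 11.8 and 5.97 ± 3.24 CPM and Mmp8 at 467 ± 346 and 121 ± 41.4 CPM. Monocyte, primary-granule, stem-cell and megakaryocyte lists were not called. Klf4, a transcription factor of monocytes that is also an early-response gene, rose from 16.4 ± 3.38 to 62.4 ± 30.8 CPM (log2 fold change 1.93, SE 0.34, edgeR adjusted p = 0.0280).

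Of 20 homing and adhesion genes, 13 were fitted lower and 7 higher in Pbrm1_KO, and the list scores differed by -0.31 with no overlap (exact permutation p = 0.0159, the smallest possible; 0.131 adjusted over lists). The erythroid, the mast, basophil and eosinophil, and the checkpoint scores separated the groups in the same way, with the same p and adjusted p. The homing list was called by camera (adjusted p = 0.0458; adjusted p = 0.458 with an estimated correlation) and in 12 of 20 alternative settings. The call was lost without Pbrm1_WT replicate 1, 2 or 5 or Pbrm1_KO replicate 1 (adjusted p = 0.118, 0.0547, 0.0786 and 0.0598). Its 1 member past the threshold, Itgb7, which encodes the beta-7 integrin, fell from 412 ± 131 to 114 ± 35.0 CPM (log2 fold change -1.86, SE 0.28, edgeR adjusted p = 0.0179). In the list of checkpoint genes and NK-cell ligands (camera adjusted p = 0.0458; adjusted p = 0.458 with an estimated correlation), Cd276 fell from 1.24 ± 0.467 to 0.292 ± 0.0758 CPM (edgeR adjusted p = 0.0429). That list's call was lost without Pbrm1_WT replicate 1 (camera adjusted p = 0.127) and without each of the 4 Pbrm1_KO libraries (0.0598, 0.0964, 0.0590 and 0.0753). The p53-target list was not called (camera adjusted p = 0.231), although Perp and the death receptor gene Fas fell, Fas from 12.8 ± 4.66 to 5.05 ± 0.212 CPM (edgeR adjusted p = 0.0481).

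Oxidative phosphorylation genes were slightly lower, with a mean log2 fold change of -0.22 over 66 genes (camera adjusted p = 7.97e-05; adjusted p = 0.534 with an estimated correlation). Ndufa4, a respiratory-chain subunit gene, was the 1 member past the threshold and fell from 168 ± 11.1 to 117 ± 8.70 CPM (edgeR adjusted p = 0.0479). With a trend in GC content and transcript length removed, the mean of this list was 0.024 and it was no longer called (camera adjusted p = 0.602). The G2/M list was the 1 list called higher, with a mean of 0.09 (camera adjusted p = 0.0458; adjusted p = 0.733 with an estimated correlation), and 0 of its 53 members passed edgeR's threshold, with 7 higher and 2 lower at an unadjusted p below 0.05, and 3 higher by DESeq2 and 15 higher and 1 lower by limma-voom. Its mean ranged from 0.020 (without Pbrm1_WT replicate 1) to 0.24 (without Pbrm1_WT replicate 5) when 1 library was left out, and was 0.013 with similar libraries summed (camera adjusted p = 0.535) and -0.031 without both Pbrm1_WT replicates 3 and 4 (0.917). The mean was larger with the trend removed (0.17, camera adjusted p = 0.00251), limma-voom (0.23, 2.39e-05) and the replicate block (0.24, 1.91e-05). The call was lost without Pbrm1_WT replicate 1, 3 or 4 or Pbrm1_KO replicate 1 or 3 (adjusted p = 0.326, 0.382, 0.119, 0.0809 and 0.0800). Ncapd2, a condensin subunit gene, stood at 283 ± 23.3 and 400 ± 26.4 CPM in Pbrm1_WT and Pbrm1_KO (edgeR adjusted p = 0.0575). The early-response list was called lower (camera adjusted p = 0.0317; adjusted p = 0.660 with an estimated correlation), with Ier5 reduced from 42.4 ± 9.27 to 19.97 ± 4.32 CPM (edgeR adjusted p = 0.0377) and Klf4 raised. Pbrm1_WT replicate 1 had the highest score of that list, 4.87, and without it the mean went from -0.46 to -0.22 and the call was lost (camera adjusted p = 0.445), as it was without Pbrm1_KO replicate 1 (0.0598) or 3 (0.177). With limma-voom the mean was -0.053 and the list was not called (camera adjusted p = 0.377). The S-phase, MYC and ribosome biogenesis, glycolysis, BCL2-family, NF-kB, SWI/SNF and DNA methylation lists were not called. Of 20 alternative settings, NF-kB was called in 5 (lowest camera adjusted p = 0.0116), MYC and ribosome biogenesis in 2 and SWI/SNF in 1.

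In all, camera called 17 of 33 lists at the preset correlation, 16 lower and 1 higher. With an estimated correlation camera called 0 lists (2 at an unadjusted p below 0.05), and fry called 0 (12 at an unadjusted p below 0.05). The score tests gave 0 lists after adjustment and 11 before it. With a smallest possible exact permutation p of 0.0159, adjustment over 33 lists leaves a call only if many lists reach that value at once. The lack of adjusted calls is therefore weak evidence. Most list members past the threshold were close to it: of the 9 fits that each left out 1 library, Itgb7 missed it in 2, Siglec5 in 6, Ikbke, H2-Oa, Klf4, Xcl1 and Fas in 7, and Cd276, Ndufa4 and Ier5 in 8, each with its direction kept.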

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

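The tests of GC content and length, of lymphoid RNA, of the Cd79b ratio, of summed libraries and of splits that keep similar libraries together were chosen after the results were seen; the counts over all drawn splits were planned.

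Single libraries stood apart from the rest of their group in 10 of 220 groups of values examined, where chance alone gives about 11. Values of the same library need not be independent, so this count does not show that no library stands apart. Every flag in the Pbrm1_KO group fell on replicate 2. That library correlated at r = 0.950 to 0.959 with the other Pbrm1_KO libraries, which correlated at 0.977 to 0.986 with each other. Pbrm1_KO replicate 2 had a stem-cell list score of 4.75 (others 4.37 to 4.39), and log2 CPM of 7.62 for Arid1b, 8.72 for Cebpa, 6.96 for Clspn and 2.71 for Osm. Pbrm1_WT replicate 1 had log2 CPM of -0.19 for Tchh and 4.27 for C1qa. Pbrm1_WT replicate 2 had a MYC and ribosome biogenesis score of 6.59, Pbrm1_WT replicate 3 a log2 CPM of -0.050 for Pdgfra, and Pbrm1_WT replicate 5 a log2 CPM of 7.41 for Siglec5.

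The first pattern is the number of genes that differed: of 100 splits of the 9 libraries into 5 and 4, only 1, the real one, gave as many genes as the real 205, and the highest of the others gave 14, so chance can be excluded for the count if the libraries are independent, which is not stated. Among the 23 drawn splits that kept Pbrm1_WT replicates 3 and 4 together, and Pbrm1_KO replicates 3 and 4 together, the real one was again the 1 with as many; with Pbrm1_WT replicates 1 and 2 and Pbrm1_KO replicates 1, 3 and 4 also kept together there were 5 splits, too few for a share under 0.05, and the highest other gave 14. A trend in GC content and transcript length as the whole cause is argued against, since 170 of the 205 genes stayed past the threshold once it was removed, when 342 genes passed. Summing similar libraries into 3 samples against 2 ended every call (smallest edgeR adjusted p = 0.171). The sums joined Pbrm1_WT replicates 1 and 2, Pbrm1_WT replicates 3 and 4, and Pbrm1_KO replicates 1, 3 and 4. Pbrm1_WT replicate 5 and Pbrm1_KO replicate 2 were kept alone. The median SE of the 205 genes rose from 0.27 to 0.41. Their median absolute log2 fold change went from 1.55 to 1.61. All 205 kept their direction, but this is largely built in, since 203 of them did not overlap between the groups. If the libraries joined in each sum share an origin, the smaller sample is the proper one and no gene passes. If only Pbrm1_WT replicates 3 and 4, and Pbrm1_KO replicates 3 and 4, share one, too many libraries were summed. A fit for that case was not made. If no libraries share an origin, the loss may come from fewer samples. The data cannot tell these apart. An effect of the knockout, a shared origin of similar libraries and any unrecorded difference in how the groups were raised or collected stay open.

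The second pattern is the lower interferon-stimulated list in Pbrm1_KO. Chance cannot be excluded: 33 of 100 splits gave the list as small a camera p at the preset correlation, the real p being 1.4e-06 and the smallest of the others 5.4e-25. The trend in GC content and length does not account for it, the mean log2 fold change being -0.61 after its removal against -0.69 before. Within the groups the interferon score rose with the mean B, T and NK score across the 9 libraries (Pearson r = 0.892, exact permutation p = 0.0181; Spearman rho = 0.80, exact permutation p = 0.0462; r = 0.970 without Pbrm1_WT replicate 1 and Pbrm1_KO replicate 1, the farthest from the median, but the first of these departs from the relation, so the rise is no support). The libraries are not shown to be independent, and with the similar pairs (Pbrm1_WT replicates 3 and 4, Pbrm1_KO replicates 3 and 4) averaged into 1 each r = 0.85 (exact permutation p = 0.0694) and rho = 0.79 (exact permutation p = 0.0764) over 7 values, while r = 0.60 without Pbrm1_WT replicates 3 and 4 (exact permutation p = 0.243), which are the highest in both scores, so that a smaller r is built in; with so few values, RNA of lymphoid cells and a knockout effect on both gene groups cannot be told apart.

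The third pattern is the loss of Cd79b. Fewer B cells in the knockout samples would lower Cd79b and its partner Cd79a by the same fold, but their log2 ratio was 3.85 ± 1.40 in Pbrm1_WT (SD, n = 5) and 0.63 ± 0.91 in Pbrm1_KO (SD, n = 4), with no overlap (exact permutation p = 0.0159, the smallest possible). Cd79a itself stood at 1.80 and 0.997 CPM. Cd79b was picked for a large decrease without overlap, so the separation of the ratio and its p are partly built in. The unequal falls of Cd79b and Cd79a are therefore weak evidence against B cells as the whole source of the Cd79b difference. The other members of the B, T and NK lists, which are at low levels, are not covered by this comparison. Expression by the blasts stays open.

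Over all lists together, 7 of 100 splits gave at least the 17 lists of the real split, the highest of the others giving 20, so chance cannot be excluded for the number of lists called at the preset correlation.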

How the results depend on the processing

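Chosen after the data were seen were the removal of the GC and length trend, the sum of similar libraries and the joint removal of Pbrm1_WT replicates 3 and 4. For the 205 genes (98 higher, 107 lower), DESeq2 gave 1093 (463, 630), limma-voom 2649 (1257, 1392), 1 surrogate variable 1167 (600, 567), the trend removal 342 (177, 165), an adjusted p below 0.01 7 (4, 3), and a log2 fold change of at least 1 56 higher. Joint removal of replicates 3 and 4 gave 16 (8, 8). Summing similar libraries, which leaves 3 against 2, gave 0 (0, 0). At an unadjusted p below 0.05 the summed samples gave 1030 genes, against 2389 in the main fit. Leaving out Pbrm1_WT replicates 1 to 5 gave 133, 60, 70, 37 and 473 genes, and leaving out Pbrm1_KO replicates 1 to 4 gave 54, 75, 54 and 9; the range was 6 to 205 higher and 3 to 268 lower. The 20 genes with the largest changes kept their direction in each of these settings in which they were tested. This is largely built in, since the naming rule takes only genes without overlap between the groups. Between 4 and 19 of them stayed past the threshold when 1 library was left out. The cause of the differences between tools was not tested.

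Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.10, 0.034, -0.12 and -0.024, and none of the Pbrm1_KO libraries correlated best with its own number. With the number as a replicate block, 6 genes were called (3 higher, 3 lower).

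Pbrm1 was lower in every setting, with log2 fold changes from -1.69 to -1.21 when 1 library was left out. It passed the threshold with DESeq2 (-1.48), limma-voom (-1.74), 1 surrogate variable (-1.47) and the trend removed (-1.50). Tet2 changed sign with limma-voom (-0.10), the trend removed (-0.038) and without Pbrm1_KO replicate 2 (-0.11, range to 0.29), and Tet3 with the trend removed (-0.014), none past the threshold.

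The 17 lists became 11 with the filter of 1 CPM in 4 libraries, 9 without marker genes of other cells (fewer lists and genes tested), 0 with an estimated correlation, 0 with fry, and 11 to 17 when 1 library was left out (11 without Pbrm1_WT replicate 1 or Pbrm1_KO replicate 1). The interferon-stimulated list kept its direction in all settings and lost its call with replicates 3 and 4 removed (-0.15, adjusted p = 0.288), with an estimated correlation (-0.69, adjusted p = 0.629) and with fry (-0.69, adjusted p = 0.232); leaving out 1 library gave -0.77 to -0.51. The GTPase list lost its call in those settings (-0.12, -0.65 and -0.65), with the 1 CPM filter (-0.40) and without Pbrm1_WT replicate 3 (-0.43, range from -0.79). Of the other called lists, limma-voom ended the calls of the checkpoint, neutrophil, macrophage, erythroid, early-response and homing lists (adjusted p from 0.0890 to 0.377), and the trend removal those of the checkpoint, neutrophil, mast-cell and oxidative phosphorylation lists (0.108, 0.0759, 0.0692 and 0.602). Without Pbrm1_WT replicates 3 and 4 the class II, dendritic-cell, stromal and G2/M calls were lost (0.105, 0.234, 0.264 and 0.917). Summing similar libraries ended the checkpoint, dendritic-cell, stromal, early-response and G2/M calls (0.0773, 0.0773, 0.0940, 0.177 and 0.535), and 1 surrogate variable the checkpoint, neutrophil, dendritic-cell and stromal calls (0.0844, 0.0551, 0.0594 and 0.0844). The replicate block ended the checkpoint, neutrophil, stromal and homing calls (0.0743, 0.0775, 0.120 and 0.0743), the 1 CPM filter the checkpoint, dendritic-cell, stromal, G2/M and homing calls (0.0870, 0.0811, 0.222, 0.0865 and 0.0527), and the removal of marker genes the checkpoint, G2/M and homing calls (0.0505, 0.0582 and 0.0505). The interferon score stayed lower and not significant in every setting, from -0.71 to -0.42 when 1 library was left out. With similar libraries summed, without Pbrm1_WT replicates 3 and 4, or within replicate numbers, the exact test has too few splits to reach 0.05. The lack of significance in those settings is therefore uninformative.

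Other list means changed sign as follows, and the cause was not tested. With limma-voom they were -0.42 for class I (adjusted p = 0.000758), -0.019 for SWI/SNF, -0.20 for primary granules, 0.29 for monocytes, 0.043 for S phase and 0.030 for glycolysis. With 1 surrogate variable they were -0.011 for granules and 0.020 for monocytes, and with the replicate block -0.018 for class I, -0.046 for granules and 0.082 for S phase. Library totals gave 0.0020 for monocytes. Without Pbrm1_WT replicates 3 and 4 they were 0.099 for nucleic acid sensing, 0.28 for stem-cell genes, 0.12 for plasma cells and -0.031 for G2/M, and with similar libraries summed 0.036 for stem-cell genes and 0.024 for plasma cells. With the trend removed they were 0.099 for monocytes, 0.055 for S phase and 0.024 for oxidative phosphorylation. When 1 library was left out, the means ranged from -0.19 (without Pbrm1_KO replicate 2) to 0.32 for class I, from -0.24 to 0.23 for granules, from -0.12 to 0.12 for monocytes (0.12 without Pbrm1_WT replicate 1, 0.030 without Pbrm1_WT replicate 5, 0.091 and 0.084 without Pbrm1_KO replicates 2 and 3), and from -0.079 to 0.080 for S phase (0.062 and 0.080 without Pbrm1_WT replicates 2 and 5, 0.040 and 0.045 without Pbrm1_KO replicates 1 and 4). Genes with a Pbrm1_WT level under 1 CPM, such as Snx7 (SE 0.82) and Jag1 (SE 0.50), have low counts in that group. The size of their fitted fold changes is therefore less certain. No setting varied the prior count of the fit.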

Other observations

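The tests of zinc-finger genes and of transcript length, and the genes named in this part, were chosen after their values were seen. Several abundant genes outside the naming rule also differed. The cell-cycle transcription factor genes Foxm1 and E2f7 rose, Foxm1 from 68.5 ± 8.89 CPM in Pbrm1_WT to 132 ± 7.61 CPM in Pbrm1_KO (edgeR adjusted p = 0.0124) and E2f7 from 18.9 ± 1.39 to 37.1 ± 6.94 CPM (adjusted p = 0.0179). Il6ra, the interleukin-6 receptor gene, rose from 195 ± 23.9 to 372 ± 54.6 CPM (adjusted p = 0.0179). Il2rg, the common chain of several cytokine receptors, fell from 116 ± 32.6 to 23.8 ± 7.65 CPM (adjusted p = 0.0124), and Alox15, a lipoxygenase gene, from 56.6 ± 31.1 to 6.54 ± 2.57 CPM (adjusted p = 0.0179).

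Zinc-finger genes, recognised by symbols beginning with Zfp, Zkscan, Zscan or Znf and a number, made up 8 of the 107 lower genes (7.48%) against 317 of 12055 tested (2.63%) and 0 of the 98 higher ones. The odds ratio for the lower genes was 3.04 (95% interval 1.27 to 6.31, Fisher's exact p = 0.00717). Zkscan17 changed most clearly, from 33.4 ± 6.14 to 5.13 ± 2.48 CPM (edgeR adjusted p = 0.00969). An excess of such genes among those reduced may exist, as a hypothesis found and tested on the same data.

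Transcripts of higher genes were longer than those of lower genes, with medians of 4399 and 2497 bases against 3330 for all tested genes (permutation p = 1e-05, the smallest that 100000 resamples give). The permutation shuffled the called genes as if they were independent, so its p does not measure the spread between libraries. After the trend in GC content and length was removed, the medians of the genes called were 3476 and 3210 bases. The removal takes out length-related differences whatever their source, so this narrowing is largely built in. Of 80 ribosomal protein genes, which are short, 75 were fitted lower, 3 of them past the threshold, with a median log2 fold change of -0.46 before and -0.20 after that removal. The smaller decrease after removal is likewise largely built in for short genes. A length-related bias between the groups may contribute to the small decreases of short, abundant genes. An effect of the knockout on these genes cannot be separated from it here.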
